A study of Mus musculus with 28 samples.

How the data were processed

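Total RNA of HC11 and 4T1 cells was extracted with TRIzol and sequenced after removal of ribosomal RNA, with NEBNext Ultra II libraries, per the labels' protocols, and gene counts of 28 libraries were used. Per the submitters' processing notes, reads were handled with fastp 0.23.2 and counted with featureCounts 2.0.1, with the mouse build GRCm39. The aligner and the strand setting are not given in the sources used here. The deposited values are whole read counts per gene, 1 file per library, with no normalisation or filter applied by the authors as far as the files show: every file listed the same 56748 Ensembl gene identifiers and all values were whole numbers. A gene and its antisense partner cannot be told apart without a strand setting. Reads that fall in identical copies appeared to be counted at each copy: the copy Gm28661 had between 0.996 and 1.00 times the count of mt-Co2 in every library. The count of Rps2-ps10 was 2.62 to 2.98 times that of Rps2, so counts of ribosomal protein genes, histones and other multicopy genes are uncertain.

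Groups were taken from the cell line and treatment labels, which gave 10 HC11 libraries with DOX, 10 HC11 libraries with DOX and DIP and 8 4T1 libraries with DOX. Libraries are numbered within a group in the order of the series, as names only: the labels give no replicate or culture, so a number pairs nothing. No pair of libraries within a group was a copy: the lowest chi-square per degree of freedom between 2 libraries of a group was 16.3. Libraries of a group were unequally alike, from 46.3 (libraries 7 and 9) to 690.3 (5 and 8) in HC11 DOX and from 30.9 (7 and 9) to 2134 (2 and 10) with DIP. The fits treated libraries as independent, and any that share a culture would make the p-values too small. Depth ran from 134117581 to 222065843 counts per library, so that a count of 0 allowed, at 3 counts of the total, between 0.0135 and 0.0224 CPM. Gene symbols came from GENCODE vM21 by Ensembl identifier, which named 52073 identifiers and left 4675 without a symbol. Names in the gene lists that this release lacks were looked up among RefSeq synonyms (GRCm38.p6). Of 625 listed names, 568 matched by symbol, 44 by synonym and 13 not at all. Since the reference build differs from that of the counts, it was used only for names, transcript lengths and the position of the gene Mtap near Cdkn2a and Cdkn2b. No coordinates are given.

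Both comparisons were fitted with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr over the 2 groups compared, TMM factors were computed, and glmQLFit with robust estimation and glmQLFTest were run with Benjamini-Hochberg adjustment. Genes were called at an adjusted p under 0.05, and at least 2-fold changes were counted besides. The standard error of a log2 fold change was its size divided by the square root of F. Biological coefficients of variation were 0.409 for DIP in HC11 and 0.301 for 4T1 against HC11. CPM values used TMM factors over all 28 libraries, and log2 CPM values a prior count of 2.

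The 23 gene lists covered lactation, hormone response, lipid synthesis, the cell cycle, the ribosome and ribosomal DNA, epithelial and mesenchymal identity, immune and stress responses and cancer genes. They were tested with camera in limma 3.58.1 on log2 CPM with an estimated correlation for each list, where at least 3 members were measured, with camera at a preset correlation of 0.01, and with fry, which tests whether the genes of a list move on balance in one direction without comparing them with other genes. The rule for genes named was, for each comparison, the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 2, a symbol that is not a predicted model, and groups that do not overlap. To these were added 21 genes of lactation, glucocorticoid response, RNA polymerase I and tumour suppression, and, for each list, the 3 called members with the largest change at that mean log2 CPM. A few values of other genes are given in the closing section, where they are marked as chosen after their values were seen.

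Counts simulated from the means, library sizes and dispersions of the real libraries, with 200 genes changed, were used to test the procedure. For DIP in HC11, with 23066 genes tested, edgeR recovered 28.4% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 3 false calls. For 4T1 against HC11, with 23104 genes tested, it recovered 59.7%, 80.6% and 95.5%, with 11 false calls. In the same simulation a list raised 2-fold, that of ribosome biogenesis, was called by all 3 list tests. Of the other lists 0 were called, except 2 by fry for 4T1. Genes were simulated independently of each other, whereas the estimated correlation of that list in the real libraries was 0.871 for DIP and 0.821 for 4T1. The simulation therefore does not show how the list tests behave on correlated genes.

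The gene lists, the rule for named genes, the main tests and the alternatives named next were fixed before the data were examined. The alternatives were DESeq2's size factors and upper-quartile factors in the edgeR test, the Wald test of DESeq2 1.42.0, limma voom, no filter beyond 1 count, a filter of at least 1 CPM in as many libraries as the smaller group, a fit of all 3 groups, surrogate variables from sva 3.50.0 (5 and 4 were used), removal of the 20 most abundant genes, and leaving out each library in turn. Fits without DIP libraries 8 and 10, and without 4T1 libraries 1 and 2, and list tests under other scalings and without those libraries, were added after the data had been seen. The comparison of both sets of fold changes used 20 random splits of the HC11 DOX libraries and 20 simulated pairs of unchanged groups. Groupings of the libraries other than the real one were tested with 100 splits per comparison, the real one included. The ribosomal RNA precursor and the transcript named in the series title were not analysed here, and whether an identifier without a symbol stands for either was not settled. One such identifier (ENSMUSG00000119584) was the most abundant in libraries of all 3 groups, at up to 2.84% of counts, and 9 of the 20 names in the structural RNA list, among them Rn18s-rs5, had no match. A few genes that the rule names are not reported here.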

Results

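The data collected were gene counts from sequencing of total RNA, with ribosomal RNA removed, of 28 libraries from a pair of mouse mammary cell lines. HC11 is an untransformed mammary epithelial line that is widely used as a model of lactogenic differentiation, and 4T1 is a mammary cancer line that metastasises in mice. There were 10 HC11 libraries with the treatment label DOX, 10 HC11 libraries labelled with DOX and DIP, and 8 4T1 libraries labelled DOX. The labels spell out neither abbreviation. In work on HC11 cells, DIP usually stands for the lactogenic hormones dexamethasone, insulin and prolactin. The series title places the libraries in a study of a transcript antisense to ribosomal DNA, in lactogenic differentiation and in breast cancer. Libraries held between 135955692 and 185616382 counts in the HC11 DOX group, between 134117581 and 222065843 in the HC11 DOX plus DIP group and between 174275141 and 198008179 in the 4T1 group, over 56748 gene identifiers. Between 29838 and 33492 genes had at least 1 count in a library. The labels name no construct and no culture. The p-values below set each difference against the spread between these libraries only, taken as independent.

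The first comparison asked how the HC11 transcriptome with DIP differed from that without it. Mki67 (ENSMUSG00000031004), a marker of cycling cells, went from 288 ± 92.4 CPM (SD, n = 10) to 10.7 ± 8.24 CPM (n = 10), a log2 fold change of -4.73 ± 0.40 (SE, adjusted p = 3.58e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 21.2 ± 5.41 to 318 ± 156 CPM, a log2 fold change of 3.93 ± 0.39 (adjusted p = 3.78e-08). Every DIP library lay beyond every DOX library for both genes. Of 23829 genes tested, 10837 passed an adjusted p of 0.05, 5838 of them higher and 4999 lower with DIP. At least 2-fold changes numbered 2561 higher and 2270 lower.

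All 30 members of the cell cycle list fell, with a median log2 fold change of -4.15. The list as a whole had p = 0.00644 and an adjusted p = 0.148 by camera with an estimated correlation. Among the 6 largest falls were Fam83d, Kif14, Bub1b and Cenpf, which act in mitosis, and Pclaf, which binds the replication clamp. Their log2 fold changes were -5.12, -4.99, -4.84, -4.81 and -4.89. Tnc, which encodes the matrix protein tenascin C, completed that set at -4.83 ± 0.33. Aurkb fell 27.8-fold, from 96.6 ± 9.06 to 3.42 ± 2.29 CPM. Of 43 replication-dependent histone genes, 17 fell and 14 rose. H2ac13, H2ac10 and H2ac15 had log2 fold changes of -4.17, -4.13 and -4.12, although near-identical copies make counts of single histone genes uncertain. In the breast cancer list 4 genes rose and 8 fell of 23 (median log2 fold change -0.20, adjusted p = 0.635 with an estimated correlation). Brca1 fell 15.1-fold and Brca2 3.46-fold, 2 genes of DNA repair, and Ccnd1 (cyclin D1) fell 2.96-fold. HC11 DOX library 5 was the lowest of its group for Mki67, Cenpf, Brca1 and Brca2.

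**Figure D1:**
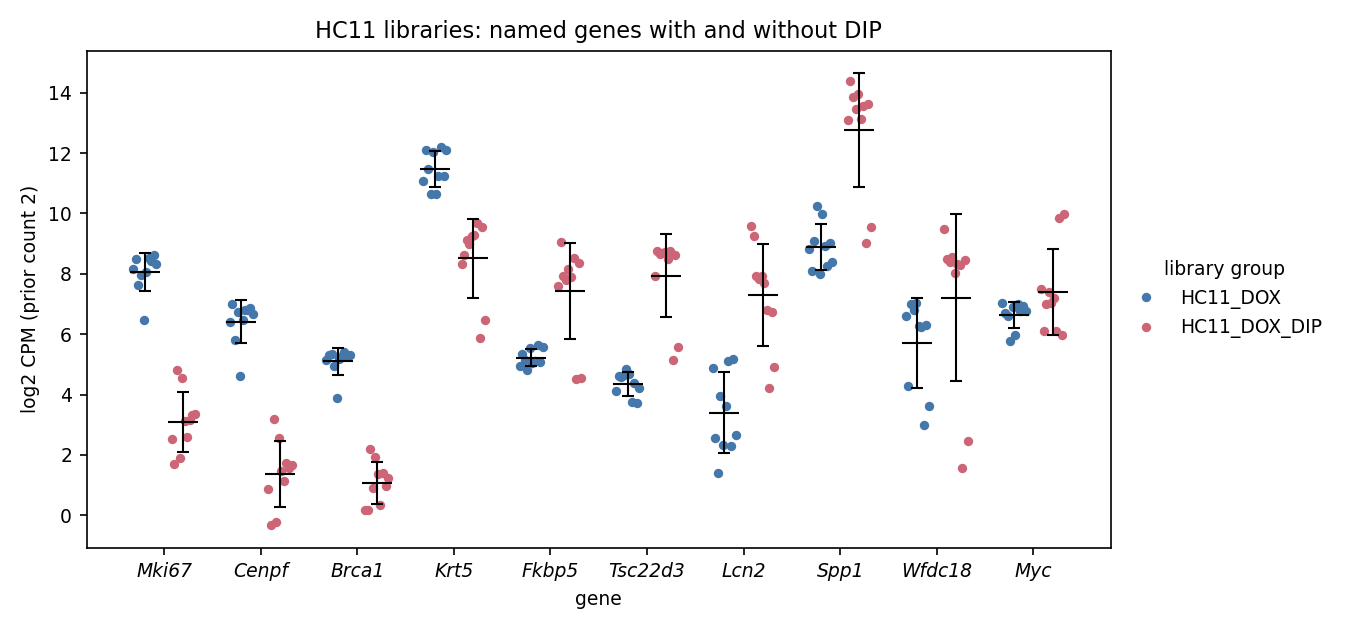
Log2 CPM of 10 named genes in each HC11 library, without DIP (blue, n = 10) and with DIP (red, n = 10). Bars give the group mean and SD. Mki67, Cenpf and Brca1 lie lower in every DIP library, and 2 DIP libraries stand apart from the other 8 in Fkbp5, Tsc22d3, Spp1, Wfdc18 and Myc.

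Among glucocorticoid targets, 18 of 25 measured members rose and 0 fell, with a median log2 fold change of 2.15. The adjusted p was 0.635 with an estimated correlation and 2.38e-06 with a preset correlation of 0.01. Fkbp5, a co-chaperone of steroid receptors, rose 6.64-fold (log2 fold change 2.73 ± 0.41, adjusted p = 1.28e-05), Lcn2, which encodes lipocalin 2, rose 17.1-fold, and Angptl4, a lipoprotein lipase inhibitor, rose 8.05-fold. The groups overlapped for Fkbp5 and Lcn2 but not for Angptl4. HC11 DOX plus DIP libraries 8 and 10 did not share the rise of the list. Their mean log2 CPM over the list was 2.50 and 2.54, while the other 8 DIP libraries lay between 4.41 and 5.41 and the DOX libraries between 2.03 and 2.53. Without those 2 libraries the list's adjusted p by camera with an estimated correlation was 0.0207. Since their low values on this same list had set them apart, a smaller p was nearly fixed by leaving them out.

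Genes of milk and its fat globule rose in part. Of 9 measured members, 7 rose and 0 fell (median log2 fold change 1.43, adjusted p = 0.707 with an estimated correlation). DIP libraries 8 and 10 did not share this rise either, with a mean log2 CPM over the list of 1.63 and 1.77, inside the range of the DOX libraries (0.63 to 2.69), while the other 8 DIP libraries lay between 3.77 and 4.73. Wfdc18, a whey acidic protein family member, went from 74.2 ± 46.5 to 304 ± 200 CPM (log2 fold change 2.06 ± 0.67, adjusted p = 0.0161, and 0.197 under limma voom), and Xdh, which encodes the xanthine oxidoreductase of the fat globule, went from 9.20 ± 8.63 to 34.7 ± 17.1 CPM. The caseins were near the limit of counting. Csn2 (beta-casein) had 20 counts in total, in 4 of the 10 DIP libraries, and 0 counts in the DOX libraries, where a count of 0 allowed up to 0.0221 CPM in the shallowest library. Csn3 had 39 counts with DIP and 3 without, and Wap had 41 and 19. None of these 3 genes passed the expression filter. Such limits cover counting error only.

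In the prolactin and STAT5 list, 8 of 24 members rose and 4 fell. Bcl6, a transcriptional repressor, rose 4.30-fold, with overlap between the groups. The kinase gene Jak2 rose 2.47-fold and Socs3, a feedback inhibitor of cytokine signalling, fell 3.03-fold, both without overlap. Stat5a had a log2 fold change of 0.97 ± 0.36 with an adjusted p of 0.0343, and leaving out single libraries moved that p between 0.00832 and 0.0713. Prlr (-0.35 ± 0.53), Elf5 (0.19 ± 0.55) and Cish (0.08 ± 0.28) did not pass the test.

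In the integrated stress and unfolded protein list 8 members rose and 8 fell of 26 (median log2 fold change 0.12, adjusted p = 0.898 with an estimated correlation). Its largest rises were those of Atf3, a stress-induced transcription factor (14.4-fold), Trib3 (6.84-fold) and Ddit3 (6.75-fold). By the rule for named genes, which takes only groups that do not overlap, Atf3 was among the 6 largest rises. So was Ppp1r15a, which encodes a phosphatase subunit of the integrated stress response. Ppp1r15a had a log2 fold change of 3.60, and 2.82 without DIP libraries 8 and 10, in which it was the highest. Spp1 (log2 fold change 4.34), Lcn2 (4.10) and Ehf (3.91) rose more than Atf3, with groups that overlapped. The other genes among the 6 largest rises by that rule were Tsc22d3, given above, Steap1 (17.0-fold), Apobr (log2 fold change 3.90) and Cystm1 (14.3-fold). Of 25 p53 targets, 10 rose and 2 fell (median log2 fold change 0.26, adjusted p = 0.596 with an estimated correlation). Btg2 rose 6.44-fold with overlap between the groups, and Gtse1, a gene of the G2 and M phases, fell 14.6-fold without overlap. Trp53 and Cdkn2a did not pass the test, at log2 fold changes of 0.45 ± 0.34 and -0.38 ± 0.17. Myc had a log2 fold change of 1.49 ± 0.48 (adjusted p = 0.0142), and 0.22 (adjusted p = 0.409) without DIP libraries 8 and 10, in which it was the highest. Without these libraries Trp53 had a log2 fold change of -0.37 (adjusted p = 0.0370).

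Keratins of the basal layer fell. Krt5 went from 3071 ± 1222 to 472 ± 256 CPM and Krt14 from 1974 ± 577 to 449 ± 222.2 CPM, and 10 of 19 basal and myoepithelial genes fell with 0 higher (adjusted p = 0.635 with an estimated correlation). DIP libraries 8 and 10 lay lowest on this list, at a mean log2 CPM of 2.39 and 2.45, against 3.42 to 4.40 in the other DIP libraries and 4.57 to 5.30 in the DOX libraries. Of 13 luminal genes, 6 fell and 2 rose. The falls included the surface antigen gene Ly6a, 6.92-fold, and Notch1, 2.46-fold. Among 27 epithelial genes, 12 rose and 3 fell. Ehf, an epithelial transcription factor, rose by 3.91 on the log2 scale. Its groups overlapped, with 3.03 to 195 CPM with DIP and 2.63 to 11.6 CPM without. Cdh1 (E-cadherin) fell from 328 ± 39.1 to 219 ± 16.0 CPM and Epcam did not pass the test at 0.04 ± 0.21. In the mesenchymal list 3 genes rose and 4 fell of 26, with Sparc up 8.12-fold and Vim not called (0.38 ± 0.61). Sparc ran from 82.0 to 9854 CPM with DIP and from 341 to 900 CPM without, so the lowest DIP library lay below every DOX library.

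Interferon and antigen presentation genes rose, 20 of 33 with 1 lower (median log2 fold change 1.06, adjusted p = 0.707 with an estimated correlation). The groups overlapped on this list, at a mean log2 CPM of 1.07 to 3.52 in the DOX libraries and 2.79 to 3.84 with DIP. Usp18 rose 6.32-fold and Oas1a 4.41-fold, with overlap between the groups, and the class I gene H2-D1 rose 4.04-fold without overlap. The secreted factors split, 8 higher and 11 lower of 25. Spp1, which encodes osteopontin, rose from 540 ± 324 to 10727 ± 6470 CPM. Its groups overlapped, at 519 to 21480 CPM with DIP and 257 to 1215 CPM without. Plau, which encodes urokinase, fell 4.16-fold without overlap. Cholesterol synthesis genes fell, 14 of 23 with 2 higher (median -0.62, adjusted p = 0.707 with an estimated correlation). Idi1 fell 3.85-fold. Fatty acid and triglyceride genes split, 5 higher and 4 lower of 24. Lpin1 rose 4.87-fold and Srebf1 2.97-fold (adjusted p = 0.00207 for Srebf1 by edgeR, and 0.0579 under limma voom). The groups overlapped for both genes, and the lowest DIP library for Srebf1 (95.8 CPM) lay below every DOX library (at least 230 CPM).

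Of 25 measured genes of RNA polymerase I and rDNA silencing, 3 rose and 8 fell. Polr1a (-0.04 ± 0.22), Polr1b (-0.07 ± 0.27), Ubtf (-0.15 ± 0.11), Rrn3 (-0.08 ± 0.16) and Baz2a (0.09 ± 0.14) did not pass the test. Without DIP libraries 8 and 10, Polr1a (-0.43, adjusted p = 0.0106) and Rrn3 (-0.32, adjusted p = 0.0310) did, and the medians of the RNA polymerase I and ribosome biogenesis lists went from -0.08 to -0.30 and from 0.10 to -0.32. Dnmt1, the maintenance DNA methyltransferase, fell from 319 ± 39.7 to 62.6 ± 16.1 CPM, and the histone methyltransferase gene Kmt5b rose 1.82-fold. Ribosome biogenesis genes numbered 1 higher and 2 lower of 40, and cytosolic ribosomal protein genes 2 higher and 7 lower of 56. DIP libraries 8 and 10 had the highest mean log2 CPM of ribosome biogenesis genes among the HC11 libraries, at 7.52 and 7.60, against at most 7.06 in any other.

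Over the 23 lists, camera with an estimated correlation called 0 at an adjusted p under 0.05 and 1 at an unadjusted p under 0.05. With a preset correlation of 0.01 it called 3 higher (glucocorticoid targets, interferon, milk) and 4 lower (cell cycle, basal, cholesterol, histones). The self-contained test fry called 11. Adjusted over the list alone, 30 cell cycle genes fell, 19 glucocorticoid targets rose and 1 fell, 21 interferon genes rose and 2 fell, and 1 basal gene rose and 11 fell.

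**Figure D2:**
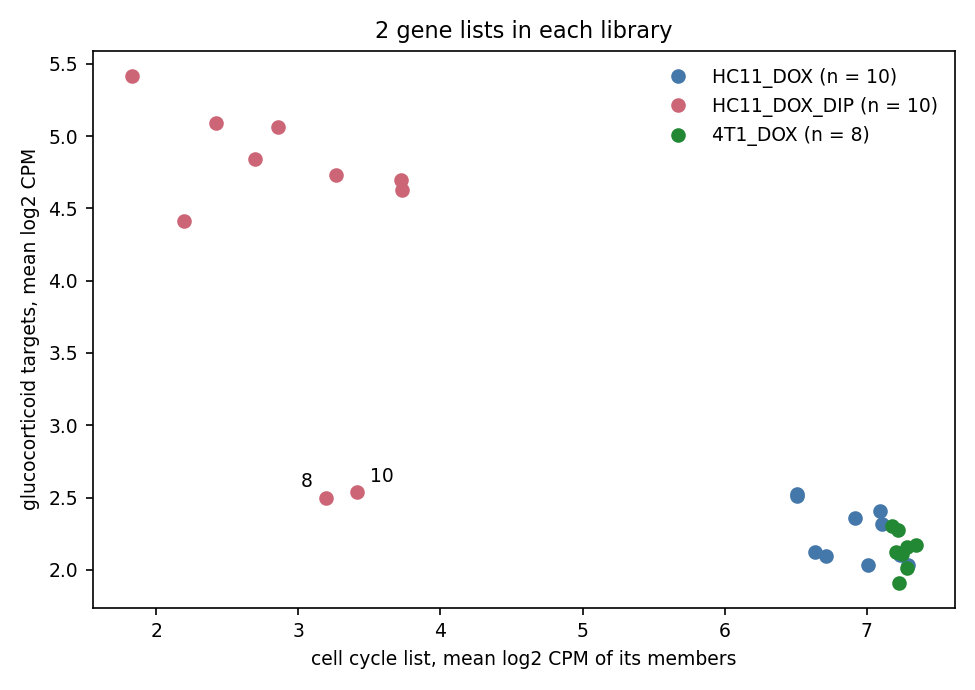
Mean log2 CPM of the cell cycle list (horizontal) and of the glucocorticoid targets (vertical) in each of the 28 libraries, coloured by group. HC11 DOX plus DIP libraries 8 and 10 (numbered) had cell cycle values of 3.19 and 3.41, and glucocorticoid target values of 2.50 and 2.54 against at least 4.41 in the other DIP libraries.

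The next comparison set 4T1 against HC11, both with the DOX label. The lines differed at most tested genes, 16688 of 23875, with 8178 higher and 8510 lower in 4T1. At least 2-fold changes numbered 3012 higher and 4787 lower. Vim (ENSMUSG00000026728), the mesenchymal intermediate filament, stood at 3417 ± 472 CPM in 4T1 (SD, n = 8) and 32.0 ± 15.2 CPM in HC11 (n = 10), a log2 fold change of 6.74 ± 0.38 (SE, adjusted p = 6.24e-12 by edgeR). The basal keratin gene Krt5 stood at 31.0 ± 31.8 CPM in 4T1 and 3071 ± 1222 CPM in HC11. The other genes of the 6 largest rises were Msln (mesothelin, 786-fold), Fbln2 (fibulin 2, 348-fold), Nes (nestin, 301-fold), Krt19 (keratin 19, 193-fold) and Cavin1 (a caveolar coat protein, 97.4-fold).

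The 6 largest falls were the collagen genes Col3a1 (-7.86 ± 0.91) and Col2a1 (-7.05 ± 0.61), the growth factor binding protein gene Igfbp3 (-6.78 ± 0.54), Xylt1 (-6.76 ± 0.44), Rtl3 (-6.73 ± 0.54) and Krt6a (-6.68 ± 0.57), as log2 fold changes. The 4T1 libraries held a low signal of genes typical of HC11. Over 256 genes above 10 CPM in HC11 and under 2% of that in 4T1 libraries 3, 5, 6, 7 and 8, the median was 4.62% of the HC11 level in library 2, 3.06% in library 1, 1.37% in library 4 and between 0.530% and 0.887% in the other 5. Without libraries 1 and 2, the log2 fold change of Krt6a was -7.78 and that of Col3a1 -8.51. Other genes far lower in 4T1 may hold the same signal, among them Krt5, at 10.6 to 96.3 CPM over the 4T1 libraries. Their falls may be understated.

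Basal and luminal markers were more often lower than higher. Of 19 basal and myoepithelial genes, 15 were lower in 4T1 and 2 higher (median log2 fold change -3.01, p = 0.0370, adjusted p = 0.291 with an estimated correlation). Trp63, the transcription factor p63 of basal cells, was at -6.06 ± 0.45 and Col17a1 at -5.99 ± 0.49. Of 13 luminal genes, 8 were lower and 3 higher, with Ly6d at -5.62 ± 0.56 and Sox9 6.27-fold lower. The epithelial list divided, with 9 higher and 15 lower of 27. Krt18 was 57.6-fold higher in 4T1, Rab25 54.0-fold lower and Epcam 2.66-fold lower, while Cdh1 did not pass the test at 351 ± 42.4 CPM against 328 ± 39.1 in HC11 (log2 fold change 0.09 ± 0.09). In the mesenchymal list, 17 of 26 genes were lower and 7 higher (median log2 fold change -2.18, adjusted p = 0.790 with an estimated correlation). Vim rose, and Col3a1 and the N-cadherin gene Cdh2 (-6.39 ± 0.49) fell.

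**Figure D3:**
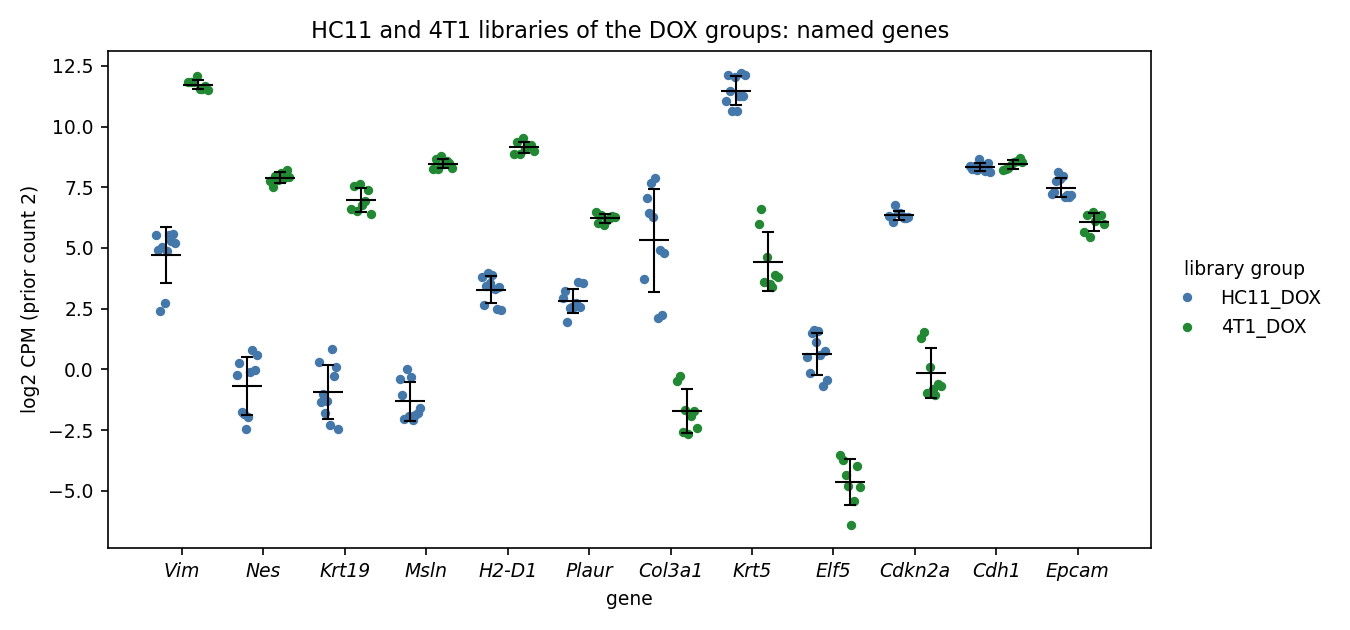
Log2 CPM of 12 named genes in each HC11 DOX library (blue, n = 10) and each 4T1 DOX library (green, n = 8). Bars give the group mean and SD. Vim, Nes, Krt19, Msln, H2-D1 and Plaur lie higher in every 4T1 library, and Col3a1, Krt5, Elf5, Cdkn2a and Epcam lower.

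Genes of ribosomal proteins and of ribosome biogenesis were more often higher than lower in 4T1. Of 56 cytosolic ribosomal protein genes, 51 rose and 0 fell, with a median log2 fold change of 0.65. Rps28 rose 2.73-fold, Rps18 2.49-fold and Rpl14 2.22-fold. Of 40 ribosome biogenesis genes, 28 rose and 0 fell (median 0.59), among them Bop1 (2.68-fold), Gnl3 (2.58-fold) and Rrp9 (2.50-fold). With an estimated correlation both lists had an adjusted p of 0.790, and with the preset correlation 1.67e-09 and 2.04e-04. Both medians stayed above 0 under every scaling tried. Of 25 genes of RNA polymerase I and rDNA silencing, 6 rose and 7 fell. Ubtf, the upstream binding factor of RNA polymerase I, rose from 152 ± 23.9 to 205 ± 11.5 CPM, Baz2a, a subunit of the nucleolar remodelling complex, fell from 78.7 ± 17.1 to 48.2 ± 6.68 CPM, and the deacetylase gene Sirt7 fell 2.67-fold. Polr1a, Polr1b and Rrn3 did not pass the test.

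Cholesterol synthesis, glycolysis and cell cycle genes were more often higher than lower in 4T1. In the cholesterol synthesis list 18 of 23 genes rose and 1 fell, with Fdps up 3.22-fold (adjusted p = 0.790 with an estimated correlation). In hypoxia and glycolysis 12 of 22 rose and 3 fell, with the enolase gene Eno1 going from 878 ± 184 to 2553 ± 205 CPM (adjusted p = 0.790). In the cell cycle list 19 of 30 rose and 2 fell (median log2 fold change 0.37, adjusted p = 0.790). Mki67 rose 1.47-fold (adjusted p = 0.0150, and 0.144 in a fit of all 3 groups), Cdc6 rose 2.15-fold, and Ccne1, which encodes cyclin E1, fell 2.68-fold. Fatty acid genes split, 8 higher and 9 lower of 24, with Scd1 4.52-fold lower.

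Secreted and immune genes were more often higher than lower. Of 27 secreted inflammatory and metastasis factors, 19 rose and 5 fell (median log2 fold change 1.79, p = 0.0317, adjusted p = 0.291 with an estimated correlation). The urokinase receptor gene Plaur rose 10.1-fold, the chemokine gene Ccl5 9.16-fold and Csf1, the macrophage colony-stimulating factor gene, 8.34-fold. Of 33 interferon and antigen presentation genes, 20 rose and 6 fell (adjusted p = 0.790). The class I genes H2-D1 and H2-K1 rose 54.4-fold and 9.26-fold, with reads that such similar genes can share, and the peptide transporter gene Tap2 rose 4.59-fold.

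The tumour suppressor genes Cdkn2a and Trp53 were lower in 4T1. Cdkn2a (ENSMUSG00000044303), which encodes the p16 and p19 inhibitors, stood at 1.15 ± 0.974 CPM against 81.5 ± 11.3 CPM in HC11, a log2 fold change of -6.16 ± 0.39 (adjusted p = 3.49e-11) that became -6.97 without 4T1 libraries 1 and 2. Trp53 stood at 46.5 ± 5.26 CPM against 134.2 ± 28.1 CPM (-1.53 ± 0.12, adjusted p = 1.29e-09). The p53 targets were divided, 7 higher and 8 lower of 22, with Cdkn1a, which encodes p21, 6.25-fold lower and Btg2 4.63-fold lower. In the breast cancer list 12 of 23 fell and 5 rose (p = 0.0379, adjusted p = 0.291), with the receptor genes Fgfr1 at -5.84 ± 0.43 and Fgfr2 at -2.90 ± 0.23, while Myc rose 2.39-fold. In the stress list 8 rose and 10 fell of 26, and the serine synthesis genes Phgdh and Psat1 rose 2.08-fold and 1.93-fold.

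In the lists of the lactation programme more genes were lower than higher in 4T1, with adjusted p of 0.805 (milk), 0.811 (prolactin and STAT5) and 0.790 (glucocorticoid targets) with an estimated correlation. Elf5, a transcription factor of milk-producing cells, stood at 1.78 ± 0.934 CPM in HC11 and had 47 counts in 7 of the 8 4T1 libraries. Prlr, the prolactin receptor gene, stood at 0.299 ± 0.253 CPM in HC11 and had 16 counts in 3 of the 8 4T1 libraries, with groups that overlapped. Of 24 prolactin and STAT5 genes 14 fell and 7 rose, with Id2 7.97-fold lower, Stat5a 1.91-fold lower and Gata3 5.65-fold higher. Of 8 milk genes measured 5 fell and 2 rose. Wfdc18 fell 32.8-fold, and Plin2 and Mfge8, of lipid droplets and the fat globule, rose 2.17-fold and 2.09-fold. Csn2 and Wap had 0 counts in the 8 libraries and Csn3 had 93. Of 24 glucocorticoid targets 13 fell and 6 rose, with Lcn2 10.9-fold and Cebpd 8.42-fold lower and Fkbp5 2.64-fold higher.

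Over the 23 lists, camera with an estimated correlation called 0 at an adjusted p under 0.05 and 3 at an unadjusted p under 0.05. With the preset correlation it called 7 higher and 2 lower, and fry called 16. Adjusted over the list alone, 51 ribosomal protein genes rose, 28 ribosome biogenesis genes rose, 19 secreted factors rose and 5 fell, and 21 cell cycle genes rose and 2 fell.

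**Figure D4:**
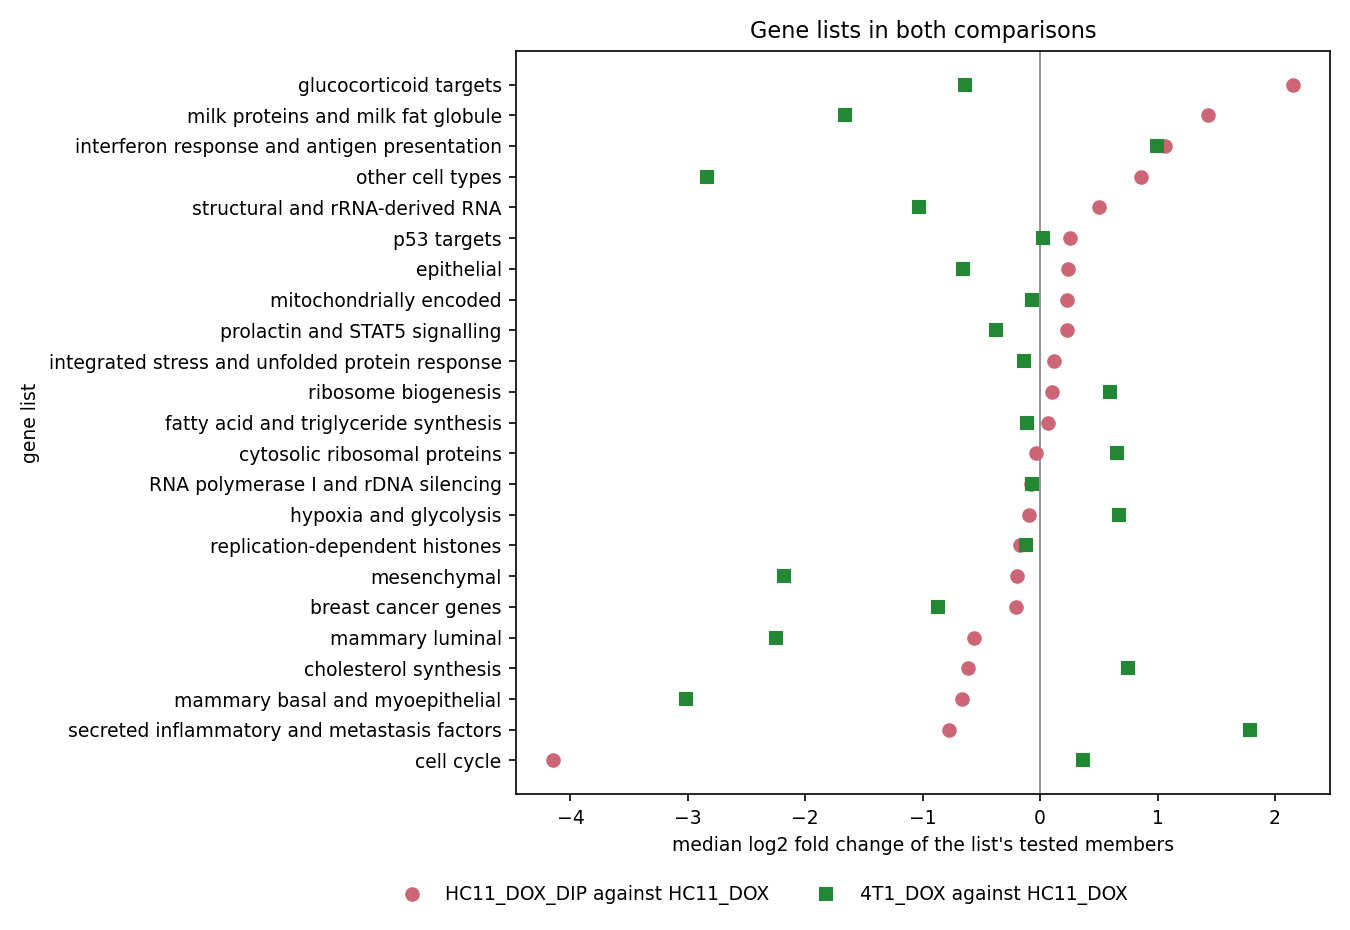
Median log2 fold change of the tested members of each of the 23 gene lists, with DIP against without in HC11 (red circles) and in 4T1 against HC11 (green squares). The cell cycle list lies at -4.15 with DIP, the glucocorticoid targets at 2.15, and in 4T1 the basal list lies at -3.01 and the secreted factors at 1.79.

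Both comparisons were then set side by side, to ask whether genes that respond to DIP in HC11 also differ between the lines. They mostly did not move together. Across the 22982 genes tested in both, Pearson's r of the log2 fold changes was 0.062 and Spearman's rho -0.064, and genes are not independent replicates. Genes higher in both numbered 1488, where independent lists would share 1798, and genes lower in both 1637, where independent lists would share 1838. Opposite changes were more frequent than independence gives, with 2365 genes higher with DIP and lower in 4T1 (2002 for independent lists) and 2039 lower with DIP and higher in 4T1 (1650). The cell cycle, cholesterol synthesis and milk lists were examples, with medians of -4.15, -0.62 and 1.43 with DIP and 0.37, 0.75 and -1.66 in 4T1. Other lists went the same way in both, among them interferon (1.06 and 0.99), basal (-0.67 and -3.01) and luminal genes (-0.56 and -2.25). All 6 were picked after their values were seen. Both comparisons used the same HC11 DOX libraries. A simulation of all 3 groups, HC11 DOX included, with equal means and independent genes gave an r of 0.420 and a covariance of 0.027. The observed covariance was 0.116, a difference of 0.088. With the HC11 DOX libraries split into 2 sets of 5, each serving one comparison, r was 0.060 on average and between -0.041 and 0.099 over 20 splits. The covariance was 0.112 on average in these splits, close to the observed one. The difference from the simulation is therefore no measure of what the shared libraries add. Over the 12640 genes with a mean log2 CPM of at least 2, r was -0.030.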

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

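The tests of explanations in this part were chosen after the results were seen. Dixon's ratio was computed for 543 sets of values, those of 154 named genes, 23 lists and 4 library measures in 3 groups, and 21 sets had a library farther from the rest than the 95% limit. Chance gives about 1 in 20, so the number of flagged sets is no more than chance would give. The ratio sets the gap between the most extreme library and its nearest neighbour against the range, so it misses libraries that lie apart together. The pair of DIP libraries with low glucocorticoid targets was not flagged on that list. The sets also share libraries and are not independent, so the count cannot show that no library is unusual. The gene values below are log2 CPM.

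The transcripts of the main milk proteins were near 0 in the DIP libraries although other genes responded, and Csn2 stood out in HC11 DOX plus DIP library 1, at -3.51 against at most -5.37 in the other libraries of its group. Too little depth is argued against by the limit that a count of 0 allows in the shallowest DIP library, 0.0224 CPM. A lack of any response to DIP is argued against by the glucocorticoid targets, whose median log2 fold change was 2.15 with 18 of 25 members higher. The highest count of any casein gene or Wap in a DIP library was 14, and a loss of such reads in alignment or counting cannot be told apart from low expression, since lost reads leave no trace in the files. No biological explanation was tested.

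HC11 DOX library 5 was the lowest of its group for Mki67 (6.47, against at least 7.63 in the others), Brca1 (3.90, at least 4.93), Brca2 (3.21, at least 4.17), Cenpf (4.62, at least 5.80) and Kmt5b (4.45, at least 5.10). The same library was the highest for Agpat1 (5.51, at most 5.07), Aurkb (6.87, at most 6.66) and Rpsa (10.89, at most 10.54). HC11 DOX library 6 was the lowest for Rpl11 (8.44, at least 8.90). In HC11 DOX library 4, mitochondrially encoded genes took 5.07% of counts, against at most 3.90% in the rest of the group, and their mean log2 CPM was 11.10 (at most 10.75). HC11 DOX plus DIP library 1 was the lowest for Agpat1 (4.605, at least 5.14), Baz2a (5.58, at least 6.25) and Gata3 (2.70, at least 3.39). Library 2 of that group was the lowest for Igfbp2 (-3.88, at least -0.88) and Phgdh (6.32, at least 7.06) and the highest for Mfge8 (8.28, at most 7.43). Library 8 of that group was the lowest for Rps28 (6.52, at least 7.17). In 4T1, library 4 was the highest for Gata3 (6.59, at most 6.26) and library 7 the lowest for mt-Nd3 (7.97, at least 8.89).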

How the results depend on the processing

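The tests without DIP libraries 8 and 10 or 4T1 libraries 1 and 2, and those of lists under other scalings, were chosen after the results were seen. No paired analysis was possible because the labels carry no replicate numbers. Under the 9 other tools, scalings and filters fixed beforehand, the genes called ranged from 7963 to 14801 for DIP and from 11823 to 20794 for 4T1 against HC11. Both were lowest with the strict filter of at least 1 CPM, which tested fewer genes, and highest with surrogate variables for DIP and with no filter, which tested more genes, for 4T1. Without DIP libraries 8 and 10, 12803 genes were called, and 10020 of these were also called in full. All 10020 kept their direction, which was nearly fixed beforehand because both fits share most of their libraries. Leaving out single libraries gave 10244 to 11438 and 16229 to 16916 genes. The 2-fold counts moved most with the filter, through the number of genes tested. With no filter, 3913 genes were higher and 3128 lower with DIP, and 4289 higher and 8191 lower in 4T1. With the strict filter, 1290 were higher and 1409 lower with DIP, and 1750 higher and 2468 lower in 4T1. Removing the 20 most abundant genes moved the median log2 fold change of all genes in 4T1 from -0.01 to -0.11.

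Of the named genes, 12 of 90 changed their side of the threshold or their direction under at least 1 alternative for DIP and 8 of 89 for 4T1. Those reversed were Elf5 with DIP, at -0.80 with surrogate variables, and Trp53 with DIP, at -0.37 without libraries 8 and 10. The cause was not tested. Calls lost under the most alternatives with DIP were those of the hypoxia list gene Bnip3 (13), Stat5a (12) and the milk list gene Muc15 (10). In 4T1 it was that of the histone gene H1f2 (9). Stat5a with DIP lost its call without any 1 of 10 libraries (DOX 1, 2, 7, 8, 9 and 10, DIP 5, 6, 7 and 9). Cdkn2a with DIP passed without DIP library 10 (-0.49), without libraries 8 and 10 (-0.55), under voom (-0.45) and with surrogate variables (-0.42), and Polr1b in 4T1 passed without 4T1 library 2 (0.51). With surrogate variables Prlr (-0.60) and Trp53 (0.20) with DIP, and Polr1a (-0.18), Polr1b (0.48), Cish (0.24) and Cdh1 (0.13) in 4T1 also passed. The number of lists called depended on the list test: for DIP, 1 without libraries 8 and 10, 7 with the preset correlation and 11 with fry; for 4T1, 9 and 16. The list called without libraries 8 and 10 was the glucocorticoid targets, whose values had set those libraries apart. The 3 other scalings called 0 lists in camera with an estimated correlation, with 1 to 3 at an unadjusted p under 0.05. The correlation of both sets of fold changes was -0.030 over genes with a mean log2 CPM of at least 2, where 958 genes were higher and 771 lower in both, and 0.020 without DIP libraries 8 and 10. With the HC11 DOX libraries split, 931 genes on average were higher in both, in fits of fewer libraries.

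Of 100 splits of the HC11 libraries into 10 and 10, only the real one (1 of 100) called as many as 10837 genes, and the highest other split called 7002. That split exchanged 2 libraries of each group. No lower share than 1 of 100 can be reached with 100 splits. The splits treat libraries as independent, so they do not exclude an effect of libraries that share a culture. For 4T1 against HC11 the real split alone (1 of 100) called 16688 genes, and the highest other called 23. With the estimated correlation the real split called 0 lists in either comparison and other splits at most 1 and 2. All 100 splits reach 0 whatever the data, so this count says nothing about chance.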

Other observations

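The tests of explanations in this part, apart from that of transcript length, were chosen after the results were seen. Of 11 structural RNA genes measured, 2 rose with DIP, Malat1 4.12-fold and Neat1 2.98-fold, and 9 were not called (adjusted p of the list 0.898). Decorin (Dcn), a proteoglycan among the markers of other cell types, rose 10.3-fold, from 5.58 ± 4.78 to 56.1 ± 61.3 CPM, and of 8 such markers measured 4 rose and 1 fell. Of 13 mitochondrially encoded genes 6 rose, among them mt-Nd4 (1.40-fold) and mt-Nd6 (1.39-fold), 6 were not called and 1 fell, mt-Nd1, from 2777 ± 232 to 1757 ± 294 CPM. In hypoxia and glycolysis 3 rose and 3 fell of 21, with Ndrg1 2.07-fold higher and Pkm 1.49-fold lower. In 4T1 the mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 were 2.04-fold and 1.56-fold lower than in HC11. The groups overlapped for both genes, in libraries from which ribosomal RNA had been removed. Of 13 mitochondrially encoded genes 2 were higher and 3 lower. Of 11 structural RNA genes 7 were lower in 4T1 and 0 higher (adjusted p of the list 0.790 by camera with an estimated correlation). Of 8 markers of other cell types 5 were lower and 2 higher, with Csf1r 1.47-fold higher.

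HC11 DOX plus DIP libraries 8 and 10 had glucocorticoid targets at the level of libraries without DIP, with a mean log2 CPM of 2.50 and 2.54. A wrong label on libraries of the DOX group is argued against by the cell cycle list, whose higher value in the 2 libraries was 3.41, while the lowest DOX library was at 6.51 with an SD of 0.29. RNA of 4T1 cells is argued against by 85 genes typical of 4T1, whose median was at most 0.509% of the 4T1 level. A transcript length bias is argued against by the targets' median deviation from the other DIP libraries, which was -2.40 or lower after the trend with length was removed and -2.62 or lower before, over 22 of their 25 members. A different treatment or culture of these libraries stays open, and no biological explanation was tested, since the labels name no construct.

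Transcripts typical of HC11 were present at a low level in every 4T1 library, most in libraries 1 and 2. HC11 material or reads carried over may be the source: of 256 genes chosen without libraries 1 and 2, at least 99.2% were higher in each of these libraries than in libraries 3, 5, 6, 7 and 8, which were used for the choice, and 83.6% in library 4, while those 5 libraries, each left out of the choice in turn, were higher than the other 4 in 5.20% to 44.5%. Library depth is argued against, since 1 of the 2 libraries had a total within the range of the other 6. The lowest value in library 2 among all 10667 genes above 10 CPM in HC11 was 1.00% of the HC11 level, that of Col3a1. That gene ran from 4.27 to 236.5 CPM over the HC11 DOX libraries, so a percent of its mean is uncertain. Expression of these genes by 4T1 cells, at levels that differ between cultures, would raise the same genes in the same libraries. It would not hold them near a single share of the HC11 level. The quartiles over the 256 genes were 3.68% and 5.46% in library 2, and 2.43% and 3.69% in library 1. These narrow ranges argue against it as the main source in those 2 libraries, which had no part in the choice. In the other libraries it cannot be told apart from carry-over. No biological explanation was tested.

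Whether 4T1 cells make any transcripts of Cdkn2a and Cdkn2b cannot be told apart from the carried-over or own signal above. As a percent of the HC11 level both genes lay within the middle 90% of the 256 genes in 8 of the 8 libraries, but both are members of that set, so this outcome was nearly fixed by the choice. Mtap, which lies close to both genes in RefSeq's annotation, was between 805% and 902% of its HC11 level. Cdkn2b and Mtap were chosen after their values were seen.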
